A study of Rattus norvegicus with 12 samples.

How the data were processed

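Gene expression was measured on 12 Illumina RatRef-12 BeadChip arrays, each hybridised with biotin-labelled cRNA made from 250 ng of total RNA. The RNA came from the pituitary or the hypothalamus of Wistar male rats on postnatal day 70, born to dams that had received the dioxin TCDD (a ligand of the aryl hydrocarbon receptor, AhR) or vehicle by mouth on gestation day 15. The sources disagree on the dose: the series text gives 1 µg per kg and the sample protocols give 1 mg per kg in corn oil, so no result is tied to a dose. Per the labels there were 4 groups of 3 arrays (pituitary vehicle, pituitary TCDD, hypothalamus vehicle and hypothalamus TCDD). The labels do not state which arrays share a litter, a dam or an animal, so p-values measure the spread between arrays.

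The deposited table held, for each of 22523 probes and each array, a signal intensity that the authors had not normalized between arrays, and a detection p-value, per the file headers. Signals were linear and never fell to 0, with lowest values of 63.6 to 72.1 and highest values of 28048.3 to 35744.2, and the smallest detection p above 0 was 0.00121. The scanner software and any background step before deposit are not given in the sources used here. A separate table deposited by the authors held normalized intensity values, which per the labels' series text were normalized for each tissue on its own, by a method that is not stated. Its columns kept the rank order of their own array's signals (Spearman rho of 1), with medians of 171.321 to 171.382 on the pituitary arrays and 169.245 to 169.276 on the hypothalamus arrays and lowest values of 127.018 and 128.669. Its scale was linear, with no centring and with the direction of the signals, and the background step or offset behind its raised lowest values stays unknown. The table was used as an alternative only.

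Probes were named through the platform annotation given with the series. Of the 22523 probes, 13793 were paired with 1 gene symbol, 0 with several, and 8730 were unnamed here. Symbols were brought up to date by gene ID through an NCBI RefSeq gene table of assembly GRCr8, which held 13752 of the named probes, and the platform's symbol was kept otherwise. The array files name no genome build, so the table was used for names only and no coordinates are given.

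Signals of each tissue's 6 arrays were background-corrected with the normal-exponential model that takes the background from the detection p-values (limma's nec, the first step of neqc, with an offset of 16), quantile normalized and put on the log2 scale. A probe was tested if its detection p was under 0.05 on at least 3 of the 6 arrays. A gene was represented by its probe with the highest mean, and unnamed probes stayed as single probes. TCDD was compared with vehicle within each tissue by limma's lmFit and eBayes, two-sided, with no block, and with Benjamini-Hochberg adjustment at 0.05. For the difference of the TCDD effect between tissues (an interaction term) and for vehicle pituitary against vehicle hypothalamus, all 12 arrays were normalized together and fitted with 4 groups, over probes detected on at least 3 arrays. The offset draws the fold of dim probes toward 1. The number of arrays, 3 per group, limits the precision of every value. A group in which a probe was detected on none of the 3 arrays has only a bound. The fold was then computed as the bright group's mean against the dim group's mean of the higher of the dim probe's own value and the lowest detected value on that array, and is written as at least N-fold.

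Before the data were examined, 35 gene lists with 690 entries were fixed, covering pituitary cell types, hypothalamic peptides, GnRH regulation, steroid signalling, sexual behaviour, dioxin response, stress, immunity, proliferation, metabolism, and markers of neighbouring tissues and other cell types. Of the entries, 582 were paired with a probe and 108 were not. Lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and the rotation test fry beside it. Too few tested genes were left in the pituitary for the thyrotrope (4), endothelial (3) and posterior hypothalamic (3) lists, and in the hypothalamus for the somatotrope (3), lactotrope (3) and corticotrope (4) lists. For each list, members were also adjusted over the list alone. That adjustment was not corrected over the lists, and a gene held by several lists is the same test repeated.

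Genes were named by a rule fixed at the same time. It took, per tissue and direction, up to 10 genes of largest fold at adjusted p under 0.05 whose groups did not overlap, filled to 10 with genes at unadjusted p under 0.01 whose groups did not overlap. It added a fixed set of reproductive, pituitary hormone, dioxin response and DNA methylation genes, and the 4 members of smallest p of each list with a result past its threshold. For the difference between tissues it took the 5 genes of smallest p per direction. Unnamed probes were counted, and those singled out in the text were chosen after their values were seen, as were the list members named for the difference between the vehicle tissues. Of the fixed set, Stil, Gh1 and Tiparp had no paired probe here, and Esr1, Pgr, Cyp1a1 and Ahrr were not detected on enough arrays of either tissue to be tested.

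The 2 tissues were compared by the Pearson correlation, across genes, of their log2 differences, with an exact permutation of the treatment labels within each tissue. Alternatives fixed beforehand were no background correction, cyclic loess, median scaling, the authors' normalized table, an offset of 50, no detection filter, a detection p under 0.01 on all arrays, 12 arrays fitted together, eBayes with trend and robust, array weights, numbers in the labels as blocks, the mean of a gene's probes, other thresholds, and leaving out each array. The list test of the difference between tissues, the lists under cyclic loess and median scaling, the lists without their member of smallest p, and the lists on members tested in both tissues were added after the data were seen. No slide was named, so no block for slide was run.

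The limma fits were tested on simulated log2 values with the real probes' means and spreads, in 10 rounds with 200 genes changed, 100 of them by 2-fold and 100 by 4-fold. The values were drawn as if already normalized and filtered, and independently for each probe. Background correction, normalization, the detection filter and the effect of correlation between probes were therefore not tested. At adjusted p under 0.05, 87.2% of 2-fold and 98.8% of 4-fold changes were recovered over the 10119 pituitary probes, with 4.81% false calls. Over the 11095 hypothalamus probes the values were 78.0%, 96.5% and 4.33%, and for the difference between tissues over 11910 probes they were 71.5%, 96.3% and 5.20%. These shares hold for 200 changed genes and for probes that vary independently. With fewer changed genes the adjusted threshold is stricter, so the shares do not apply to comparisons with few calls. On the real arrays 12 pituitary and 17 hypothalamus probes differed by over 2-fold at an unadjusted limma p under 0.05, while 0 and 1 passed adjustment. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with matplotlib 3.10.9 were used, with a random seed of 20.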

Results

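Transcript levels were measured in the pituitary and hypothalamus of adult male rats whose mothers had received the dioxin TCDD or vehicle in late gestation. The series text states the question as which genes keep an altered expression into adulthood that is tied to defects in sexual behaviour. Each of the 4 groups held 3 arrays. The pituitary arrays detected 9934 to 10371 of the 22523 probes (44.1% to 46.0%), and the hypothalamus arrays detected 10852 to 11438 (48.2% to 50.8%). The median signal per array lay between 108.1 and 123.6.

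The vehicle arrays of the 2 tissues carried the transcripts of the tissues named in their labels. Pituitary hormone genes were far higher in the pituitary. Lhb, the beta subunit of luteinizing hormone, was 271-fold higher (log2 difference 8.08, SE 0.307, limma adjusted p = 2.46e-10), Prl, prolactin, was 221-fold higher, Fshb at least 58.5-fold, the lineage factor Pou1f1 at least 60.3-fold and the GnRH receptor Gnrhr at least 20.3-fold. Tshb was 18.8-fold and Pomc 6.84-fold higher in the pituitary. The pituitary signals of Tshb, Pomc, Prl and Lhb lay at 52.9% to 96.7% of the highest on their array, and saturation, which would make these folds too small, was not excluded. The probe of Cga, the shared glycoprotein hormone subunit, was only at least 1.09-fold higher, detected on 2 of the 3 pituitary vehicle arrays and on 0 of the hypothalamus vehicle arrays. It averaged 5.45 (log2) in the pituitary vehicle arrays, where Lhb averaged 14.2, Tshb 14.8 and Fshb 11.2. The probe may not report the gene, so its values are not read as the level of Cga. Peptide genes of hypothalamic neurons ran the other way: Pmch was at least 606-fold, Sst at least 75.5-fold, Trh at least 57.6-fold and Hcrt at least 56.0-fold higher in the hypothalamus, with Avp 35.2-fold, Oxt 24.0-fold and Gnrh1 at least 3.44-fold higher. Glial and myelin genes were also higher there, with Gfap at 62.5-fold, Mbp at 81.2-fold and Mog at least 52.7-fold. Mbp was detected on 1 of the 3 pituitary vehicle arrays, and Lhb and Prl on 2 of the 3 hypothalamus vehicle arrays, so their folds are approximate.

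By list, all 10 gonadotrope genes and all 7 corticotrope and melanotrope genes tested were higher in the pituitary, as were 5 of 7 somatotrope and 4 of 5 lactotrope genes. Of 7 thyrotrope genes, 3 were higher in the pituitary and 2 in the hypothalamus. In the hypothalamus, 23 of 30 neuropeptide genes, 18 of 19 pan-neuronal genes, 16 of 17 oligodendrocyte genes and 11 of 14 astrocyte and tanycyte genes were higher, while 3 of the neuropeptide genes were higher in the pituitary. Over all 11910 probes in the joint fit, 7656 differed between the tissues at adjusted p under 0.05, 4251 higher in the pituitary and 3405 higher in the hypothalamus. Of these, 1215 and 1450 differed by at least 2-fold.

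Pituitary gene expression after maternal TCDD was first set against vehicle. The difference of smallest p was in Pde10a, a phosphodiesterase of cyclic nucleotides (probe ILMN_1361915), whose log2 intensity was 8.39 ± 0.27 in the vehicle arrays and 9.82 ± 0.023 in the TCDD arrays (SD, n = 3 each), a 2.68-fold difference. Cyp1b1, a cytochrome P450 induced by dioxin through AhR, was 2.55-fold higher, and Fetub, the liver glycoprotein fetuin B, was 2.37-fold higher. Fos, an immediate early transcription factor, was 2.68-fold lower, and the somatostatin receptor gene Sstr2 was 1.93-fold lower. In each of these genes the 3 TCDD arrays lay on one side of the 3 vehicle arrays, and none passed the correction over all genes.

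Of 10119 probes tested by limma in the pituitary, 0 passed adjusted p under 0.05, while 612 had an unadjusted p under 0.05 (277 higher and 335 lower with TCDD), against 506 that chance alone gives. At that p, 39 differed by at least 1.5-fold, 20 higher and 19 lower. With arrays scaled to a common median in place of quantile normalization, 465 probes had an unadjusted p under 0.05 and 22.8% of them were higher. With eBayes with trend and robust 3 probes passed, and with array weights 1. The 2 groups did not overlap for 1121 probes (11.1%), where chance gives 10%. Pde10a came closest to the threshold, with a log2 difference of 1.42 (SE 0.136, adjusted p = 0.0529). It passed in 6 alternative settings with all arrays, with adjusted p from 0.000304 (eBayes with trend and robust) to 0.0207 (detection on all arrays), and without vehicle array 1 (adjusted p = 0.00733). Mmadhc in the pituitary, a gene of cobalamin metabolism, had a difference of 0.72 (SE 0.0921, 1.64-fold, adjusted p = 0.237), which passed without background correction, on the authors' table and with trend and robust (adjusted p = 0.0208, 0.0217 and 0.00535). Sstr2 (-0.95, SE 0.145, adjusted p = 0.324) passed with trend and robust (adjusted p = 0.0283). A call of Cyp1b1 or Fos rested on leaving out 1 array. Cyp1b1, at 1.35 (SE 0.318, adjusted p = 0.552), reached 1.80 without TCDD array 2 (adjusted p = 0.00386), and Fos, at -1.42 (SE 0.225, adjusted p = 0.352), reached -1.71 without TCDD array 1 (adjusted p = 0.00497).

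The other pituitary genes named for their fold, among those at an unadjusted p under 0.01 whose groups did not overlap, also missed the threshold, with adjusted p from 0.494 to 0.700. Higher with TCDD were Fxyd3 (0.77), the light neurofilament gene Nefl (0.77), Tesk2 (0.73), the interferon-induced chemokine Cxcl9 (0.60), Nat14 (0.58) and Svil (0.58). Lower were Ptgds, which makes prostaglandin D (-1.03), Prkcq (-1.03, detected on 1 of 3 TCDD arrays), the fatty acid binding protein gene Fabp7 (-1.02), the activity-regulated gene Arc (-0.74), Sntn (-0.67, detected on 1 of 3 TCDD arrays), the growth factor gene Igf2 (-0.64), Scd (-0.59) and Zfp870 (-0.58). Pituitary hormone genes differed by less than the spread between arrays: Lhb by -0.01 (95% interval -0.213 to 0.201), Fshb by 0.12, Prl by -0.01, Pomc by 0.03 and Tshb by -0.10. Their signals, apart from Fshb (5.89% to 7.80%), were a large part of the highest signal on the same array, from 52.9% for Lhb to 96.7% for Tshb, and saturation, which hides differences, was not excluded. Gnrhr differed by -0.15, Dnmt1 by -0.02, Dnmt3a by 0.13, Ahr by 0.05 and Oxt by -0.04. When 1 array was left out, these hormone and other values ran from -0.30 (Gnrhr without vehicle array 2) to 0.26 (Fshb without vehicle array 3). Avp was 0.58 higher (adjusted p = 0.808). The Cga probe was near the detection limit, and its difference of 0.01 says little about the gene. Kiss1, Cyp19a1 and Gnrh1 were not detected on enough pituitary arrays to be tested.

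**Figure D1:**
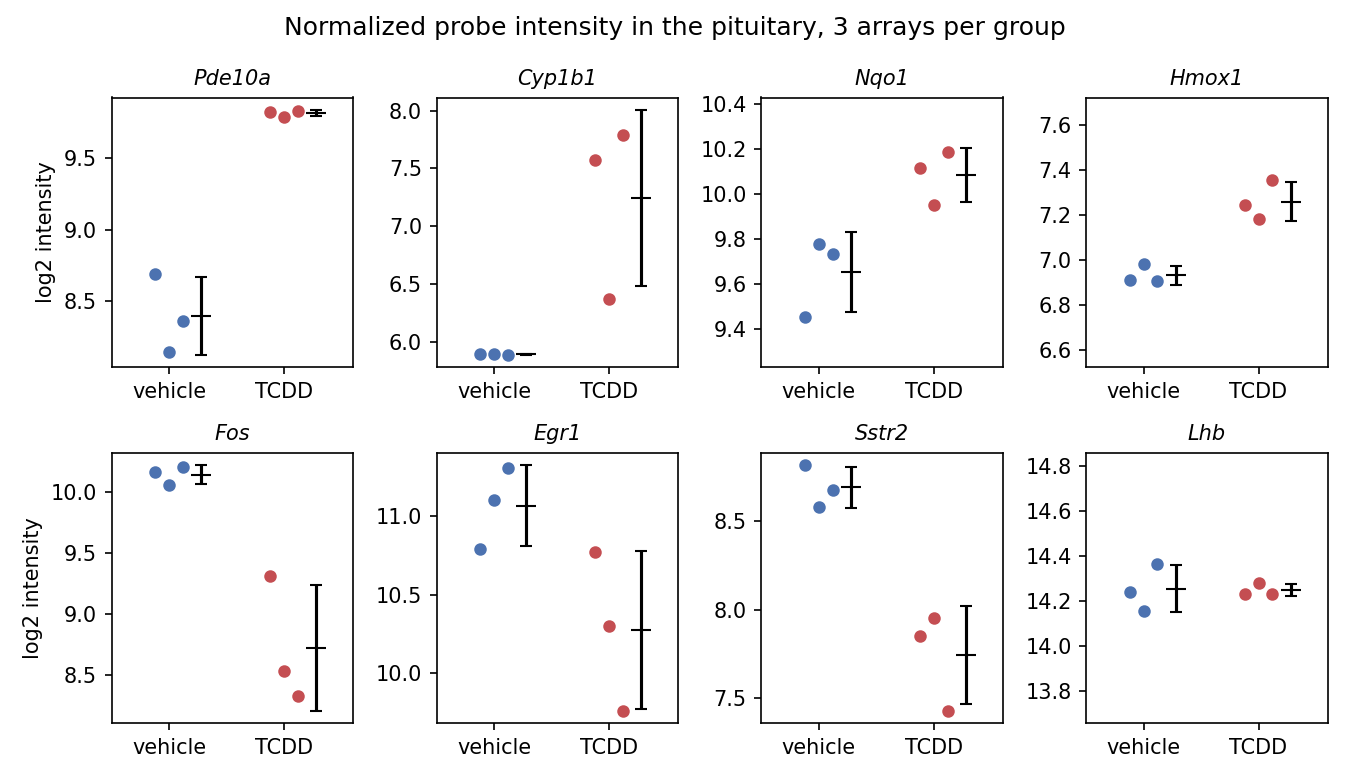
Normalized log2 intensity of 8 genes on the 6 pituitary arrays, with a point per array and the mean ± SD of the 3 vehicle and the 3 TCDD arrays. Pde10a and Cyp1b1 lie higher and Fos and Sstr2 lower on all 3 TCDD arrays, while Lhb lies between 14.16 and 14.37 on all 6 arrays.

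Dioxin response genes were the pituitary list with the most members past the threshold when adjusted over the list alone. Cyp1b1 (2.55-fold), the quinone reductase gene Nqo1 (1.35-fold) and the heme oxygenase gene Hmox1 (1.25-fold) passed adjusted over the list alone (adjusted p = 0.0176 each), against 0 over all genes, and all 3 were higher on every TCDD array than on every vehicle array. Of the 9 AhR target genes tested, 7 were higher with TCDD, though 4 with median scaling, and the list did not pass camera (adjusted p = 0.0664, and 0.707 with an estimated correlation). Cyp1a1 and Ahrr were below the detection filter in both tissues.

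Of 32 lists tested in the pituitary, 3 passed camera with the preset correlation. The immediate early genes fell as a group (adjusted p = 0.0168, and 0.707 with an estimated correlation): 11 of 17 were lower, with a mean log2 difference of -0.27, including Fos, Arc, Egr1 (-0.79) and Dusp1 (-0.63, or -0.40 without TCDD array 2). Adjusted over the list alone, 2 of them passed (Fos and Arc), against 0 over all genes. The markers of striatum, septum and cortex rose (adjusted p = 0.00789, and 0.606 with an estimated correlation), with 8 of 9 higher, a mean of 0.30 and a median of 0.16. The mean was 0.15 without Pde10a. Pde10a passed adjusted over the list alone (adjusted p = 4.7e-05), while Nrgn (0.43, or 0.23 without TCDD array 1 and 0.72 without TCDD array 2), Drd1 (0.21) and Rgs9 (0.14, or 0.09 without TCDD array 3 and 0.25 without TCDD array 1) did not. The interferon and MHC genes rose (adjusted p = 0.0403, and 0.707 with an estimated correlation), with 15 of 19 higher and a mean of 0.08. With median scaling 13 of 19 were higher and the mean was 0.03. In this list 0 members were past the threshold adjusted over the list alone. Its members of smallest p were the chemokine gene Cxcl10 (0.49, or 0.30 without TCDD array 2) and the MHC class II genes RT1-Ba and RT1-Da (0.34 and 0.30, or 0.23 and 0.17 without vehicle array 1) and RT1-DMb (0.17).

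The list calls of the immediate early and the interferon and MHC genes depended on single arrays. With the member of smallest p taken from all 3 lists together, each list missed the threshold (camera adjusted p = 0.0985, 0.0985 and 0.0997), a check added after the data were seen. Those members were picked by their p in these same data, so the check could hardly do other than weaken a call. It does not show that a call rested on 1 member alone. The rotation test fry kept 1 of the 3 lists, the striatum, septum and cortex list (adjusted p = 0.0155). The immediate early mean moved to -0.08 without vehicle array 3 (adjusted p = 0.589), to -0.19 without TCDD array 2 (adjusted p = 0.131) and to -0.48 without vehicle array 1. The interferon and MHC mean was -0.07 without vehicle array 1 (adjusted p = 0.904), 0.03 without TCDD array 2 (adjusted p = 0.212), 0.07 without TCDD array 3 (adjusted p = 0.0946), 0.17 without vehicle array 2, 0.13 without vehicle array 3 and 0.13 without TCDD array 1.

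The lists of pituitary cell types did not pass. In the gonadotrope list 7 of 10 genes were lower (adjusted p = 0.603), in the somatotrope list 4 of 7 (adjusted p = 0.603), in the lactotrope list 4 of 5 (adjusted p = 0.264) and in the corticotrope and melanotrope list 4 of 7 (adjusted p = 0.556). Sstr2 passed adjusted over the somatotrope list alone (adjusted p = 0.00112), where Rxrg stood at 0.46 and Neurod4 at 0.33 (0.29 and 0.14 without vehicle array 1) and Ghrhr at -0.22 (-0.07 without TCDD array 3). Stem and folliculostellate genes were higher in 7 of 9 cases (adjusted p = 0.452). Glucocorticoid-responsive genes were higher in 10 of 12 (adjusted p = 0.0788), and circadian clock genes in 7 of 9 (adjusted p = 0.264; 5 of 9 with median scaling). Meninges and fibroblast markers were lower in 7 of 11 (adjusted p = 0.137), with Ptgds past the threshold adjusted over the list alone (adjusted p = 0.0115), and Igf2, Mgp (-0.34, or -0.13 without TCDD array 3) and Fmod (-0.21, or -0.10 without TCDD array 1 and -0.34 without vehicle array 3) not. Among pan-neuronal genes 8 of 14 were higher (adjusted p = 0.518), with Nefl past the threshold adjusted over the list alone (adjusted p = 0.0299). Gap43 stood at -0.31, Syt1 at -0.16 and Nefm at 0.11, which ran from -0.50 to -0.14, from -0.22 to -0.07 and from 0.07 to 0.18 when 1 array was left out. Neural lobe and pituicyte markers had a mean of 0.15 and a median of -0.01, with 4 of 9 higher, or 5 with cyclic loess (adjusted p = 0.452).

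The remaining pituitary lists had adjusted p between 0.452 and 0.781 and 0 members past the threshold adjusted over the list alone. Among them, with means above 0, members were higher in 8 of 11 microglia and leukocyte markers, 7 of 11 astrocyte markers (4 of 11 with median scaling), 7 of 11 thyroid hormone pathway genes, 10 of 16 cell cycle genes and 8 of 15 neuropeptide genes. With means below 0, members were lower in 25 of 40 ribosomal protein genes, 12 of 23 heat shock and ER stress genes, 7 of 11 choroid plexus genes, 6 of 11 GnRH regulation genes, 5 of 8 sexual behaviour genes, 7 of 13 imprinted genes and 3 of 5 thalamus markers. Oligodendrocyte genes were lower in 4 of 7 cases with a mean of 0.04, red blood cell markers (mean 0.03, median -0.02) and preoptic markers were higher in 4 of 8 cases each, and 5 of 10 sex steroid, 8 of 13 DNA methylation and 18 of 32 mitochondrial genes were higher, with means that turned negative with median scaling.

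In the hypothalamus the gene whose function bears most directly on the question was Gnrh1, which encodes the releasing hormone of the gonadotropins. Its log2 intensity (probe ILMN_1373686) was 7.36 ± 0.24 in the vehicle arrays and 6.20 ± 0.40 in the TCDD arrays (SD, n = 3 each), a 2.24-fold lower mean with all 3 TCDD arrays under all 3 vehicle arrays. Mx1, an interferon-induced antiviral GTPase, was 2.83-fold higher, Mob4, a kinase-regulating scaffold protein, was 1.95-fold higher, and Rap1gds1, an exchange factor for small GTPases, was at least 2.04-fold higher, being detected on 0 of the 3 vehicle arrays and all 3 TCDD arrays. The forebrain homeobox genes Dlx5 and Lhx6 were 1.84-fold and 1.77-fold lower, with Lhx6 detected on 1 of the 3 TCDD arrays. No named gene passed the correction over all genes, and the 1 probe that did, ILMN_1374322, is unnamed here.

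ILMN_1374322 fell by 2.62 on the log2 scale (6.16-fold, SE 0.12, limma adjusted p = 0.000205), from 8.70 ± 0.087 to 6.08 ± 0.16 (SD, n = 3 each). When all 12 arrays were fitted together its difference was -2.58 and missed the threshold (adjusted p = 0.0779), so that 0 hypothalamus probes passed in that fit, and on the authors' table it was -1.34 (adjusted p = 0.00106). Of 11095 probes tested, 595 had an unadjusted p under 0.05 (299 higher and 296 lower), against 555 by chance, and 80 of them differed by at least 1.5-fold (29 higher and 51 lower). With median scaling, 640 had an unadjusted p under 0.05 and 73.1% of them were higher. The groups did not overlap for 1208 probes (10.9%), where chance gives 10%. Mob4 in the hypothalamus (0.96, SE 0.101) and Rap1gds1 in the hypothalamus had an adjusted p of 0.0596 each. Mob4 passed in 7 alternative settings (adjusted p = 0.00944 to 0.0366) and Rap1gds1 with trend and robust or array weights (adjusted p = 0.045 and 0.0176). Mx1 (1.5, SE 0.375, adjusted p = 0.883) passed without TCDD array 2, at 2.01 (adjusted p = 0.0141).

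Gnrh1 had a log2 difference of -1.17 (SE 0.213, 95% interval -1.65 to -0.675), with an adjusted p of 0.883 over all genes and a range of -1.38 to -0.997 when each array was left out. Further genes lower with TCDD on every array, each with an adjusted p of 0.883, were Cpxm2 (-1.14), the matricellular protein gene Ccn3 (-1.08), Dlx5 (-0.88), Cbr3 (-0.84), Lhx6 (-0.82, or -0.54 without vehicle array 1), Igfbp6 (-0.74), Armc8 (-0.67), the peptide gene Nmb (-0.65) and Fundc2 (-0.61). Higher on every array were Gstm4 (0.64), Itprid2 (0.63), Mmadhc (0.62), Xylb (at least 1.33-fold), Ctnna2 (0.56), Zfp692 (0.56) and Ywhag (0.52). Oxt, the oxytocin gene, was 1.88-fold lower, but its groups overlapped (-0.91, SE 0.398, adjusted p = 0.883), and without TCDD array 3 the difference was -0.51. Avp differed by -0.45, Cyp1b1 by 0.50, Pomc by 0.23, Cyp19a1, which encodes aromatase, by 0.14, Kiss1 by 0.03, Nqo1 by -0.06, Ahr by -0.11, Dnmt1 by 0.00 and Dnmt3a by -0.44, none of them past the threshold. These values moved with single arrays. Cyp1b1 was 0.18 without TCDD array 1 and 0.89 without TCDD array 2, and Pomc -0.12 without vehicle array 1 and 0.46 without vehicle array 2. Dnmt3a was -0.05 without TCDD array 1 and -0.74 without TCDD array 3, and Avp -0.23 without TCDD array 2, and the values of Cyp19a1, Kiss1, Nqo1, Ahr and Dnmt1 ran from -0.29 to 0.25. Pituitary hormone transcripts varied widely between hypothalamus arrays of a group, with differences of -0.67 (SE 0.901) for Prl, -0.03 (SE 1.11) for Tshb and -0.13 (SE 0.406) for Lhb. When 1 array was left out these ran from -1.47 to -0.18, from -1.17 to 1.15 and from -0.59 to 0.34.

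**Figure D2:**
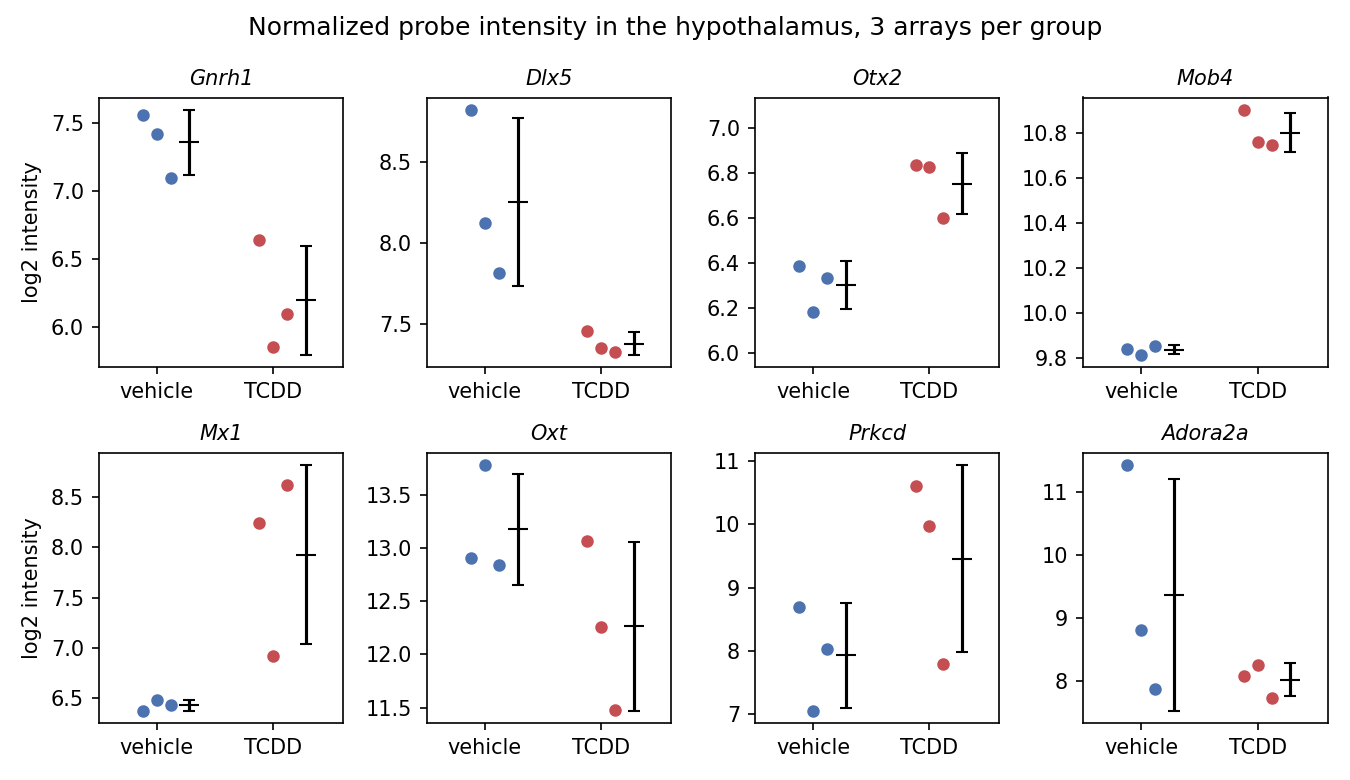
Normalized log2 intensity of 8 genes on the 6 hypothalamus arrays, with a point per array and the mean ± SD of the 3 vehicle and the 3 TCDD arrays. Gnrh1 and Dlx5 lie lower and Mob4, Mx1 and Otx2 higher on all 3 TCDD arrays, while the Oxt, Prkcd and Adora2a values of the groups overlap.

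The GnRH regulation list had members on both sides. Adjusted over the list alone, 3 passed, against 0 over all genes: Gnrh1 (adjusted p = 0.0116) and Dlx5 were lower and the homeobox gene Otx2 was higher (0.45), while Dlx1 (-0.34, or -0.23 without TCDD array 2) did not pass. As a whole 11 of 20 genes were higher, with a mean of -0.06 and a median of 0.02 (camera adjusted p = 0.698). The list includes Stil, a gene the study is held to have drawn from these arrays, and is not independent evidence in that respect, though Stil had no paired probe here. Gnrh1 also passed adjusted over the neuropeptide list alone (adjusted p = 0.0168), where Tac1 stood at -0.44 and 15 of 29 genes were higher (camera adjusted p = 0.573; mean -0.07, median 0.02). It passed adjusted over the preoptic and anterior list alone as well (adjusted p = 0.00636), where Synpo2 was at 1.12 (0.66 without TCDD array 1 and 1.78 without TCDD array 3), Rgs16 at 0.69 (0.40 and 1.13) and 6 of 11 genes were lower (camera adjusted p = 0.722, with a mean that changed sign with median scaling). The passes of Gnrh1 adjust the same limma p-value over overlapping lists, so they are not separate support.

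Of 32 lists tested in the hypothalamus, 4 passed camera with the preset correlation, and 0 with an estimated correlation or with fry. Markers of the thalamus, which adjoins the hypothalamus, rose: all 10 were higher, with a mean log2 difference of 0.83 (adjusted p = 4.16e-06, and 0.899 with an estimated correlation), among them Prkcd (1.53), Tcf7l2 (1.01), Lef1 (0.72) and Kcnc2 (0.55, and 0.69 and 0.23 on dimmer probes). Markers of striatum, septum and cortex fell: all 9 were lower, with a mean of -0.68 (adjusted p = 0.000935, and 0.899 with an estimated correlation), among them Adora2a (-1.35), Drd1 (-0.81), Rgs9 (-0.73) and Ppp1r1b (-0.59, and -0.15 on a dimmer probe). Interferon and MHC genes rose, with 15 of 18 higher and a mean of 0.31 (adjusted p = 0.00328, and 0.899 with an estimated correlation), led by Mx1, Cxcl10 (0.73), Irf7 (0.61) and Mx2 (0.53). Meninges and fibroblast markers fell, with 11 of 12 lower and a mean of -0.30 (adjusted p = 0.0322, and 0.977 with an estimated correlation), among them Col1a2 (-0.70), Ogn (-0.62), Igfbp2 (-0.59) and Ptgds (-0.40). Adjusted over each of the 4 lists alone, 0 members passed, as over all genes.

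Both neighbour lists varied between arrays of a group. The striatum, septum and cortex mean was 11.2 on vehicle array 1 against 9.38 to 9.77 on the other vehicle arrays, and without vehicle array 1 the list moved by -0.13 and missed the threshold (adjusted p = 0.174), while without vehicle array 3 it moved by -1.05. Without vehicle array 1 Adora2a stood at -0.32, Rgs9 at -0.29, Drd1 at -0.19 and Ppp1r1b at -0.16. The thalamus list moved by 0.48 without TCDD array 1 and by 1.28 without TCDD array 3 and passed in each case, with Prkcd at 0.96 and 2.37, Lef1 at 0.47 and 0.94 and Kcnc2 at 0.32 and 0.80. Without TCDD array 3 the interferon and MHC mean was 0.18 (adjusted p = 0.101), with Irf7 at 0.23 and Mx2 at 0.32, and without TCDD array 2 it was 0.49, with Irf7 at 0.95. The meninges call ended without vehicle array 3 (-0.12, adjusted p = 0.630) or TCDD array 2 (-0.02, adjusted p = 0.987), on the authors' table (adjusted p = 0.0779), without the detection filter (adjusted p = 0.0908) and without its member of smallest p (adjusted p = 0.0786), and its mean was -0.55 without TCDD array 1. Without TCDD array 2 Col1a2 stood at -0.36, Ogn at -0.32, Igfbp2 at -0.27 and Ptgds at -0.06. Gnrh1, Dlx5 and Oxt were measured in the same 6 blocks of tissue.

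**Figure D3:**
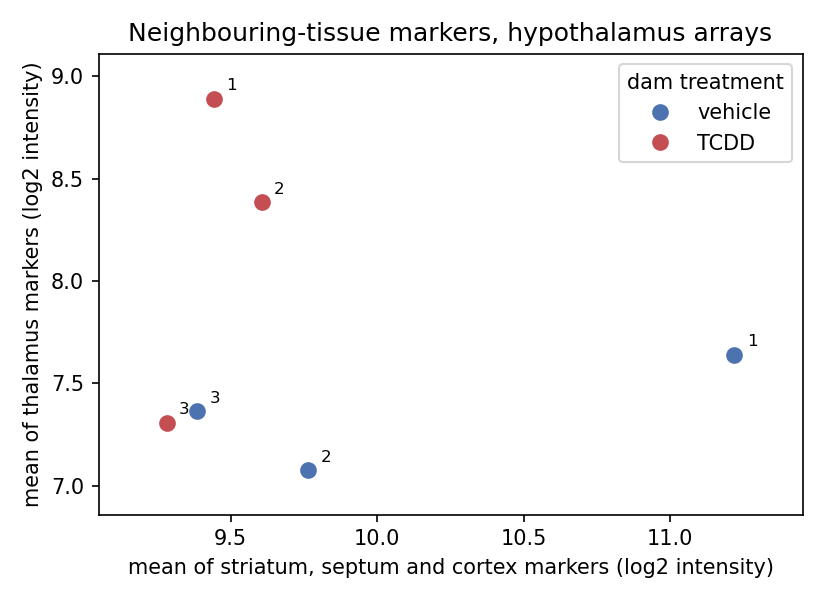
Mean log2 intensity of the striatum, septum and cortex markers (horizontal axis) and of the thalamus markers (vertical axis) on the 6 hypothalamus arrays, a point per array, numbered by replicate. TCDD arrays 1 and 2 have the highest thalamus means (8.89 and 8.39) and vehicle array 1 the highest striatum, septum and cortex mean (11.2), while TCDD array 3 lies beside the vehicle arrays.

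Several other hypothalamus lists leaned one way without passing. All 12 thyroid hormone pathway genes were lower, or 9 of 12 with median scaling, with a mean of -0.19 (adjusted p = 0.0786), and the smallest adjusted p over the list alone was 0.740. Of the sexual behaviour genes, which the series text makes the question, 7 of 10 were lower, with a mean of -0.36 and a median of -0.24 (adjusted p = 0.0786), and 0 passed adjusted over the list alone. This list shares Drd1 with the striatum, septum and cortex markers, and the Drd1 difference shrank without vehicle array 1, as given above. How far neighbouring tissue sets the lean of this list was not tested. Immediate early genes were lower in 12 of 17 (adjusted p = 0.0786). Red blood cell markers were higher in 5 of 8 (adjusted p = 0.149), with Ahsp (0.90, or 0.56 without TCDD array 3) and the globin gene Hbb-b1 (0.99) past the threshold adjusted over the list alone (adjusted p = 0.0491), and Hbb (0.41, or 0.10 without vehicle array 2) and Slc4a1 (-0.14, or -0.03 without TCDD array 3) not. Among glucocorticoid-responsive genes Nfkbia (0.47) passed adjusted over the list alone (adjusted p = 0.0371). Mt1 (-0.47), Fkbp5 (-0.40, or -0.26 without vehicle array 1) and Ddit4 (0.25, or 0.16 without TCDD array 2) did not and 7 of 12 were higher (camera adjusted p = 0.678; the list's mean turned negative with cyclic loess).

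In the hypothalamus the AhR target genes were split evenly, 4 of 8 higher (adjusted p = 0.885), with Cyp1b1 at 0.50. Gonadotrope genes were lower in 6 of 7 (adjusted p = 0.195), and endothelial markers were higher in 5 of 7 and neural lobe markers lower in 6 of 10 (adjusted p = 0.523 each). The other lists had adjusted p from 0.678 to 0.999 and 0 members past the threshold adjusted over the list alone. With means above 0, members were higher in 11 of 19 pan-neuronal, 16 of 23 heat shock and ER stress, 7 of 12 DNA methylation, 5 of 8 posterior hypothalamic, 6 of 11 circadian clock, 8 of 14 astrocyte, 19 of 34 mitochondrial and 6 of 9 pituitary stem genes. With means below 0, members were lower in 12 of 17 oligodendrocyte, 7 of 12 microglia, 7 of 11 sex steroid, 24 of 40 ribosomal protein and 8 of 13 imprinted genes, the last with a mean that changed sign with median scaling. Thyrotrope genes were lower in 4 of 6 cases, or 2 with median scaling. Cell cycle genes were higher in 6 of 11 with a mean of 0.02 and a camera direction of lower, and choroid plexus genes were higher in 6 of 12 with a mean of 0.01 and a median of -0.03.

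The 2 tissues were then compared for their response. With all 12 arrays in 1 fit, the TCDD effect was lower in the hypothalamus than in the pituitary for Rerg (-0.75, SE 0.145), Lcat (-0.68) and Wnt10b (-0.60), and higher for Sstr2 (0.88, SE 0.201), Otx2 (0.82) and Schip1 (0.58). In this fit the pituitary and hypothalamus differences with TCDD were 0.52 and -0.23 (Rerg), 0.13 and -0.55 (Lcat) and 0.37 and -0.23 (Wnt10b). They were -0.95 and -0.07 (Sstr2), -0.39 and 0.44 (Otx2) and -0.39 and 0.19 (Schip1). The other 4 genes of smallest p are given no size, since each was below detection in at least 1 group. Gnrh1 was lower with TCDD in the hypothalamus (-1.13) and was detected on 0 pituitary arrays, and Fetub was higher with TCDD in the pituitary (1.27) and was detected on 0 hypothalamus arrays. The MHC gene RT1-N3 was detected on 0 of the 3 pituitary TCDD arrays, and Rap1gds1 on the 3 hypothalamus TCDD arrays alone. None passed: of 11910 probes limma called 0 at adjusted p under 0.05, with 737 at an unadjusted p under 0.05, a smallest adjusted p of 0.567 and 1 call each without pituitary vehicle array 1 and without pituitary TCDD array 1.

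Across the 9467 probes tested in both tissues, the log2 differences had a Pearson r of 0.038 and a Spearman rho of -0.0649 (two-sided exact permutation p = 0.8 for r over 100 label splits; 1 correlation was tested). The correlation is across genes, which are not independent replicates, and 47.5% of the probes had the same sign in both tissues. Without pituitary vehicle array 2 or 3 or hypothalamus vehicle array 3 the r turned negative (-0.0147, -0.0340 and -0.0384), and without pituitary vehicle array 1 it was 0.158. At an unadjusted p under 0.05 in each tissue, 39 probes were shared, 24 in the same and 15 in opposite directions, against 27.3 for independent lists of 560 and 461. The labels do not say whether an animal or litter gave both tissues. If so, a difference between animals could show in both, and the lists would not be independent. Of the genes named here, chosen after their values were seen, Egr1 had lower means in both tissues (-0.79 and -0.51) and Cxcl10 higher in both (0.49 and 0.73), while Otx2 was lower in the pituitary (-0.38) and higher in the hypothalamus (0.45).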

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

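The list test of the difference between the tissues, with its tests on fewer members, was chosen only after the result was seen. It singled out 2 of 35 lists whose TCDD difference was not alike in the hypothalamus and the pituitary. The striatum, septum and cortex markers differed by -0.69 in the hypothalamus and by 0.30 in the pituitary, a difference of -0.98 over 9 genes (camera adjusted p = 0.000168, and 0.955 with an estimated correlation), and it was -0.43 without hypothalamus vehicle array 1 (adjusted p = 0.00134) and -0.85 without Pde10a (adjusted p = 0.00147). The 10 thalamus markers differed by 0.81 in the hypothalamus and by -0.01 in the pituitary, a difference of 0.82 (adjusted p = 0.000185, and 0.955 with an estimated correlation), with 0.48 without hypothalamus TCDD array 1 (adjusted p = 0.0244) and 1.25 without hypothalamus TCDD array 3. Only 5 of the 10 passed the detection filter in the pituitary, so for the others the difference restates the hypothalamus change, and on those 5 it was 0.90 (adjusted p = 0.0469).

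In the TCDD hypothalamus the thalamus markers lay higher and the striatum, septum and cortex markers lower, and the gap between the 2 means differed by 1.52 between the groups. That gap also ranged by 1.56 within the vehicle group and by 1.42 within the TCDD group, so the larger range was 1.03 times the difference between the groups, which is in line with blocks of tissue that were dissected differently from animal to animal. Without vehicle array 1, 0.73 of the difference was left (1.11), which leaves open how far a single array sets the gap as a whole. The striatum, septum and cortex mean was 11.2 on vehicle array 1 and 9.28 to 9.77 on the other arrays, so that list's change rested mostly on this array. The thalamus mean was 8.89 and 8.39 on TCDD arrays 1 and 2 and 7.08 to 7.64 on the other arrays. The 4 lists past the threshold in the hypothalamus were matched by 6 of the 10 splits of the 6 arrays, the real one included. The count of 4 was thus no higher than other groupings of these arrays commonly gave, and 10 splits could give no share under 0.05. The split of vehicle array 1 with TCDD arrays 1 and 2 from the rest gave 15 lists, the highest count among the other splits. All were counted with the preset correlation. Whether the arrays hold a structure other than the exposure was not tested. A difference in brain tissue brought about by maternal TCDD was not tested and stays open.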

How the results depend on the processing

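The list tests without the member of smallest p, on members tested in both tissues, under cyclic loess and under median scaling, and the list test of the difference between tissues were chosen only after the data were seen. Of the alternative values of named genes, 2106 stayed on their side of the threshold, 23 passed where the reported value did not and 1 lost its call. Among these values 44 changed sign, in genes whose reported unadjusted p was 0.05 or more. Leaving out 1 array moved the difference by over 1.5 times, or turned it, in 26 of 52 named pituitary genes, 35 of 62 named hypothalamus genes and 0 of the 10 genes named for the difference between tissues. Of the values of reported lists, 109 kept both, 29 lost the call and 1 reversed. The cause was not tested for any change given here unless stated.

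In the pituitary the reported count of 0 probes was 2 without background correction and on the authors' table, 1 with an offset of 50, 1 with detection on all arrays, 3 with eBayes with trend and robust and 1 with array weights. At looser thresholds it was 1 (adjusted p under 0.10) and 39 (unadjusted p under 0.05 and 1.5-fold). Leaving out 1 array gave 0 to 3, with 3 without vehicle array 1, 2 without TCDD array 1, 1 without TCDD array 2 and 2 without TCDD array 3. It stayed 0 with cyclic loess, median scaling, no filter, 12 arrays together and the mean of a gene's probes.

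In the hypothalamus the reported count of 1 probe was 2 without background correction, on the authors' table, with an offset of 50, with no filter and with detection on all arrays, 0 with all 12 arrays fitted together, and 3 with trend and robust and with array weights. It was 3 at adjusted p under 0.10 and 80 at an unadjusted p under 0.05 and 1.5-fold. Leaving out 1 array gave 1 to 3, with 2 without vehicle array 2, 3 without TCDD array 2 and 2 without TCDD array 3.

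The 3 pituitary lists past the threshold became 0 with an estimated correlation, 1 with fry, 5 with median scaling, on the authors' table, without background correction and with no filter, 0 without each list's member of smallest p, and 2 to 5 when 1 array was left out (5 without vehicle array 3, 2 without TCDD array 2 or 3). The interferon and MHC mean reversed to -0.0651 without vehicle array 1 and reached 0.171 without vehicle array 2. The 4 hypothalamus lists became 0 with an estimated correlation, 0 with fry, 7 with median scaling and 3 to 9 when 1 array was left out (9 without vehicle array 1). The 2 lists of the difference between tissues became 0 with an estimated correlation and 2 to 4 when 1 array was left out (4 without pituitary vehicle array 1).

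The count of 0 probes for the difference between tissues was 0 to 1 when 1 array was left out, and 0 in each other setting run. The tissue contrast of 7656 probes was 7455 (cyclic loess) to 8176 (no filter), and 7121 to 7638 when 1 array was left out. The cross-tissue correlation was 0.0254 to 0.0513 on the authors' table, without background correction and with no filter, and -0.0384 to 0.158 when 1 array was left out. It reversed to -0.0147 without pituitary vehicle array 2, -0.0340 without pituitary vehicle array 3 and -0.0384 without hypothalamus vehicle array 3.

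Groups shared replicate numbers, but same-numbered arrays correlated by 0.0716, 0.186 and 0.07 in the pituitary, each best with its own number, and by 0.112, 0.0957 and 0.259 in the hypothalamus, not all over 0.1, so they were taken to share only a number. With the replicate number as a block the counts were 0 probes and 4 lists in the pituitary, 1 probe and 5 lists in the hypothalamus, 0 for the difference between tissues and 7617 for the tissue contrast. The numbers in the titles are another numbering, shared by 2 pairs in each tissue. In the pituitary these 2 pairs also share their replicate number, so their correlations are the same values again and the 2 numberings cannot be told apart there. These pairs correlated by 0.186 and 0.07 in the pituitary and by 0.251 and 0.135 in the hypothalamus, each vehicle array best with the TCDD array of its title number, which is a hint from the data and not from the design, and pairing by title number stays open. With the number in the titles as a block the counts were 4 probes in the pituitary and 2 in the hypothalamus. Arrays of the same letter and number as a random block had a correlation of -0.141 and gave 0 probes for the difference between tissues. A block for slide was not run. Dim probes are limited by signal over background, since the offset draws their folds toward 1.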

Other observations

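The preoptic marker test, the tests of ILMN_1349205 and ILMN_1374322, the test of best partners on separate sets of probes and the tests of single pairs of the same name were chosen only after the results they bear on were seen, as were the genes of this part.

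Ephx2, the soluble epoxide hydrolase gene, had lower means with TCDD in both tissues, by a log2 difference of -1.68 in the pituitary (SE 0.537, adjusted p = 0.752) and -2.04 in the hypothalamus (SE 0.659, adjusted p = 0.883), and after normalization all 3 TCDD arrays lay below all 3 vehicle arrays in the pituitary, while in the hypothalamus TCDD array 2 lay above vehicle array 3. Ephx2 passed in the pituitary without TCDD array 1 (-2.44, adjusted p = 0.000855) and with the title numbers as blocks (-2.51, adjusted p = 0.0226), and in the hypothalamus without TCDD array 2 (-2.93, adjusted p = 0.0195). The signal of Ephx2 was of 2 kinds rather than graded. In the hypothalamus it was 548.1 to 968.8 on the vehicle arrays, 604.5 on TCDD array 2, and 173.7 and 163.8 on TCDD arrays 1 and 3. In the pituitary it was 237 to 268.9 on the vehicle arrays, 238.6 on TCDD array 1, and 102.3 and 104.3 on TCDD arrays 2 and 3. Tshb, the thyrotropin subunit gene, varied in the hypothalamus from 602.2 to 3120.6 on the vehicle arrays and from 388.5 to 7642.7 on the TCDD arrays, with signals of 24432.7 to 30636.5 in the pituitary, and Prl varied in the hypothalamus from 106.2 to 377.5.

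Among the 39 probes at an unadjusted p under 0.05 in each tissue, Mmadhc was higher with TCDD in both (0.72 in the pituitary and 0.62 in the hypothalamus), as were Mob4 (0.46 and 0.96), Nfkbia, an inhibitor of NF-kappaB (0.42 and 0.47), and Hid1 (0.38 and 0.43). The peptide gene Nmb was lower in both (-0.95 and -0.65), as was Fundc2 (-0.38 and -0.61). With the settings reported, 0 of these genes passed the correction over all genes in either tissue, while Mmadhc in the pituitary and Mob4 in the hypothalamus passed without background correction (adjusted p = 0.0208 and 0.0108), on the authors' table (0.0217 and 0.00944) and with trend and robust (0.00535 and 0.0152).

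A lower Gnrh1 in the TCDD hypothalamus could come from blocks that held other amounts of neighbouring tissue. With the mean of the striatum, septum and cortex markers as a covariate, 0.892 of the Gnrh1 difference was kept (-1.04, SE 0.238), and with the thalamus markers 1.18 of it (-1.38, SE 0.268). This argues against either share as the whole cause, but weakly, since each fit had only 6 arrays. Vehicle array 1 stood apart on the first covariate (11.2), and TCDD arrays 1 and 2 were highest on the second (8.89 and 8.39). A smaller share of the whole preoptic and anterior hypothalamus should lower the other markers of that list too. Yet 9 of them had a median of -0.0961 (mean -0.014, SE 0.113, 5 lower and 4 higher) against the -0.582 needed. This argues against an even loss of that whole region as the whole cause only as far as the 9 genes stand for the region, which was not tested. The homeobox genes Dlx5 and Lhx6, lower in the same blocks, and Otx2, higher there, were not part of this check. The 9 did not include Esr1 or Moxd1, and a loss confined to the part that holds the Gnrh1 cells was not tested and stays open. The lists were not fitted together. An effect of maternal TCDD on Gnrh1 is a hypothesis, since the gene did not pass over all genes.

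Probes with large steps between single arrays may mark differences between animals that do not follow the exposure. For ILMN_1349205, 3.61 higher with TCDD in the hypothalamus (adjusted p = 0.27, or 4.31 and 0.000149 without TCDD array 3) and 2.12 higher in the pituitary, the arrays of the pituitary vehicle group alone ranged over 5.02, which is in line with that explanation without excluding an effect of exposure. ILMN_1374322, 2.62 lower in the hypothalamus, ranged over 1.96 within the pituitary vehicle group, where it was detected on 2 of 3 arrays against 0 of 3 TCDD arrays (difference of means -1.33), which leaves it open. On the 100 probes varying most in both tissues, 2 of 4 checks found an array closest to the array of the same letter and number in the other tissue: neither did in the vehicle pair (-0.536), which argues against 1 animal there, and both did in the TCDD pair (0.414), the TCDD arrays of high Ephx2, though not on each of 2 sets of the probes, so that pair stays open. For 4 of 6 pituitary arrays the best partner was mutual on the first set and the same on the second. Whether it was mutual on the second set was not checked, and animals or litters shared under other numbers stay open.

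Other splits of the arrays were counted for the remaining comparisons. In the pituitary 7 of 10 gave at least the real 3 lists (highest other 4). In the hypothalamus 2 of 10 gave at least 1 probe (highest other 3), and for vehicle pituitary against vehicle hypothalamus 1 of 10, the real one with 7656 probes (highest other 1). In each of these cases 10 splits are too few for a share under 0.05. With 7 of 10 splits giving at least 3 lists, the pituitary list count was no higher than other groupings of the arrays commonly gave. A real count of 0 probes is met by every split, so the 10 of 10 splits in the pituitary (highest other 3) and the 100 of 100 for the difference of the TCDD effect between tissues (highest other 6) say nothing about chance.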
